A study of Mus musculus with 20 samples.

How the data were processed

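RNA sequencing was done on 20 libraries of ear tissue from C57BL/6 mice, made from oligo(dT)-selected RNA and sequenced on the MGISEQ-2000. The libraries fall into 4 groups of 5, with and without SB415286 in the AD model and in the ACD model, and the groups were taken from the sample labels alone. The numbers in the library titles did not pair injected and control mice, so no pairs were formed. The authors provided 1 table per model. Each table holds expected counts per gene, which the authors estimated and did not normalise, and FPKM values per gene and library, which the authors scaled by effective length and by M assigned fragments. Per the labels, HISAT, HISAT2, Bowtie2 2.2.5 and RSEM 1.2.8 were used, with the mouse assembly GRCm38.p6 and a human assembly also listed, and without the role of each tool. The ACD table also holds mean deposited expected counts over parts of the groups, which matched controls 1, 4 and 6 and SB415286 libraries 5, 7 and 8 within 0.01 counts and served only for an alternative. No other column was analysed.

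Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group at its default settings and libraries were scaled by TMM. The AD table holds 19234 genes, of which 15149 were tested, and the ACD table holds 19501, of which 15150 were tested. Each comparison used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (robust fit, 2-sided), and a gene passed at an adjusted p under 0.05. The difference between the models was tested as an interaction in 1 fit of all 20 libraries and 4 groups, over 15700 of the 18835 genes in both tables. Normalised reads are given as counts per M (CPM) with TMM factors, and log2 fold changes carry the standard error of the fit. Gene coordinates come from the RefSeq annotation of GRCm38.p6, in which 19177 AD and 19442 ACD identifiers were found.

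Gene lists for 35 pathways and cell types were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. The rule names Gsk3a, Gsk3b, Ctnnb1 and Axin2 in each comparison, and the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM and a symbol other than a predicted gene. Where fewer than 5 genes passed, the 10 genes with the smallest p were added. From each list described, it names up to 4 members past the threshold or otherwise the 2 with the smallest p. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and adjustment over the lists of a comparison. This gave 33 lists in each model and 34 for the difference, since B cell markers had too few tested members within each model and the tables hold no mitochondrial genes. The same test with an estimated correlation and the rotation test fry were run beside it, and list members were also adjusted over the list alone. A list score is the mean log2 CPM of the list's members in a library, compared between groups with exact 2-sided permutation tests, which at 5 against 5 cannot give a p below 0.00794. Fold changes of both models were correlated across genes, which are not independent replicates.

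The alternatives were the scaling factors of DESeq2 (RLE) and upper quartile scaling, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter of at least 1 CPM in at least 5 libraries, the title number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of at least 1 FPKM in 5 libraries, 1 fit of all libraries, and each library left out in turn. Further alternatives chosen after the data were seen left out 2 libraries of a model together, kept only the libraries behind the authors' means, or tested the lists under other scalings. The counts of genes and of lists past the threshold and the correlation between the models were also compared with 100 splits of the libraries, the real split among them, and the gene counts of each model with all 126 splits. Tested on simulated data with the same sizes, the AD, ACD and difference tests recovered 77%, 82% and 64% of genes changed by 1 on the log2 scale, and called 7 of 14851, 12 of 14844 and 5 of 15399 unchanged genes. The simulated genes varied independently of each other, the changed ones had at least 1 CPM, and no library was out of place. These rates may therefore not hold for the real libraries.

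Library totals were 18.2 to 20.9 M counts (M, mega) in the AD model and 18.8 to 20.2 M in the ACD model. No 2 libraries of a group were copies of each other: counts of each pair differed by at least 11.4 times the variance of counting alone. Intervals given for ratios of reads are exact 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.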

Results

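Gene expression was measured by RNA sequencing in ear tissue of mice from 2 skin disease models, which the labels call AD and ACD without spelling the names out. SB415286, an inhibitor of the kinase GSK3, was injected into the abdomen at 0.7 mg/kg in the AD model and at 2 mg/kg in the ACD model, and ears were taken 4 h later. These doses follow the sample labels and the design text, while the protocol text names the AD model for both. Each model had 5 libraries from injected mice and 5 from controls, 20 libraries in 4 groups. The sample labels call the controls untreated, and the design text calls them vehicle controls. Total counts (M, mega) were 18.2 to 20.9 M in AD SB415286 libraries and 19.7 to 20.6 M in AD controls. They were 19.4 to 20.2 M in ACD SB415286 libraries and 18.8 to 20.1 M in ACD controls. Between 17363 and 17726 genes had reads in an AD library and between 17429 and 17825 in an ACD library.

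The AD comparison asked how inhibition of GSK3 changed gene expression in ears of AD model mice. Beta-defensin transcripts, which encode antimicrobial peptides of the epidermis, rose with SB415286: Defb4 by 1.64 ± 0.31 on the log2 scale (SE, n = 5 per group), Defb3 by 1.61 ± 0.32 and Defb14 by 0.83 ± 0.11. S100a3, a calcium-binding protein of the hair cuticle, had the largest rise among genes past the threshold with at least 1 CPM, 2.07 ± 0.43, from 2.57 ± 0.828 CPM (SD, n = 5) in controls to 10.8 ± 6.99 CPM. Gsr and Hmox1, antioxidant genes, rose by 0.96 ± 0.15 and 0.75 ± 0.15. Ky and Myl2, genes of skeletal muscle, fell (-2.87 ± 0.48 and -2.67 ± 0.45). The amount of muscle in the samples was not measured, so these falls cannot be told from less muscle in the samples. Ppp1r3c, which targets a phosphatase to glycogen, fell by 1.85 ± 0.27, from 32.3 ± 10.3 to 8.98 ± 2.40 CPM. Cd207, the lectin langerin of Langerhans cells, fell by 2.03 ± 0.42, from 9.41 ± 5.14 to 2.30 ± 0.763 CPM. With 1 library left out, Defb4, Defb3, S100a3, Gsr, Hmox1, Ky, Myl2, Ppp1r3c and Cd207 each passed in only 2 of 10 fits. These were the fits without SB415286 library 7 and without control 6.

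Over the 15149 genes tested in the AD model, 89 rose and 98 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Their median size was 0.80 on the log2 scale. Their adjusted p ran from 0.0254 to 0.0493, and 185 of the 187 were above 0.03. The other large rises were Amd2 (1.94 ± 0.37), the keratin-associated gene Krtap21-1 (1.67 ± 0.34), Lrtm2 (1.60 ± 0.30), the keratin Krt90 (1.55 ± 0.29), Serpina11 (1.48 ± 0.20), the immune ligand Raet1e (1.46 ± 0.24) and Ankrd66 (1.26 ± 0.26). Among the other large falls were the muscle genes Mylk4 (-2.65 ± 0.42), Mstn (-2.18 ± 0.41), which encodes myostatin, and Synpo2l (-2.10 ± 0.34). Chodl (-2.49 ± 0.45), Cmtm5 (-2.39 ± 0.49), the cartilage lectin Clec3a (-2.27 ± 0.45) and the progestin receptor Paqr7 (-2.25 ± 0.41) completed the 10 largest falls. For the muscle and cartilage genes among them, the amount of these tissues in the samples was not measured. In 175 of the 187 genes all 5 SB415286 libraries lay on 1 side of all 5 controls. The 187 were called on these same libraries, so this is no added support. It held for 704 genes (4.65%) of those tested, and chance gives it for 0.794%. Genes are not independent, and 3 of 126 splits of the libraries reached 704, the real split among them. Transcripts of the target kinases did not pass: Gsk3a was at -0.04 ± 0.09 and Gsk3b at 0.15 ± 0.14. SB415286 inhibits the GSK3 protein, so these transcripts are no check of its action. Ctnnb1, which encodes beta-catenin, at 0.07 ± 0.09, and the Wnt feedback gene Axin2 at -0.42 ± 0.21 (adjusted p = 0.287) did not pass either. S100a3 lies on chromosome 3 at 90560356 to 90602706 (Entrez Gene 20197, GRCm38.p6), Defb4 on chromosome 8 at 19198704 to 19201547 (56519). Ky lies on chromosome 9 at 102505755 to 102546247 (16716), Ppp1r3c on chromosome 19 at 36731731 to 36736604 (53412) and Cd207 on chromosome 6 at 83671207 to 83677857 (246278). Reads shared between similar genes such as the beta-defensins were not examined.

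Control library 6 of the AD model correlated more with the SB415286 libraries than with the other controls (median r 0.975 against 0.960), and SB415286 library 7 correlated with both groups alike (0.947 with controls, 0.948 with its own). They also stood out in list scores, given in mean log2 CPM. For skeletal muscle genes library 7 scored 1.96, against 5.02 to 6.60 in the other SB415286 libraries, and for cartilage genes control 6 scored 3.38, against 4.87 to 5.45 in the other controls. Without both, 1796 genes were higher and 2098 lower, and all 187 genes remained among these 3894. These 2 libraries were left out because they lay toward the other group. Leaving them out draws the groups apart, so the higher count and the kept genes are no added support. The count also rested on single libraries. It was 1122 without SB415286 library 7 and 1423 without control 6, but 1 without SB415286 library 2 and 21 without library 6. It was 0 without SB415286 library 3 or 4 or without control 1, 2, 4 or 5 (2226 to 2661 genes at an unadjusted p under 0.05 by edgeR). With all libraries 1235 genes passed by DESeq2, 3588 by limma voom with quality weights and 48 without the filter, and the balance tilted to falls under upper quartile scaling (66 higher, 104 lower) and on FPKM (64 and 156).

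**Figure D1:**
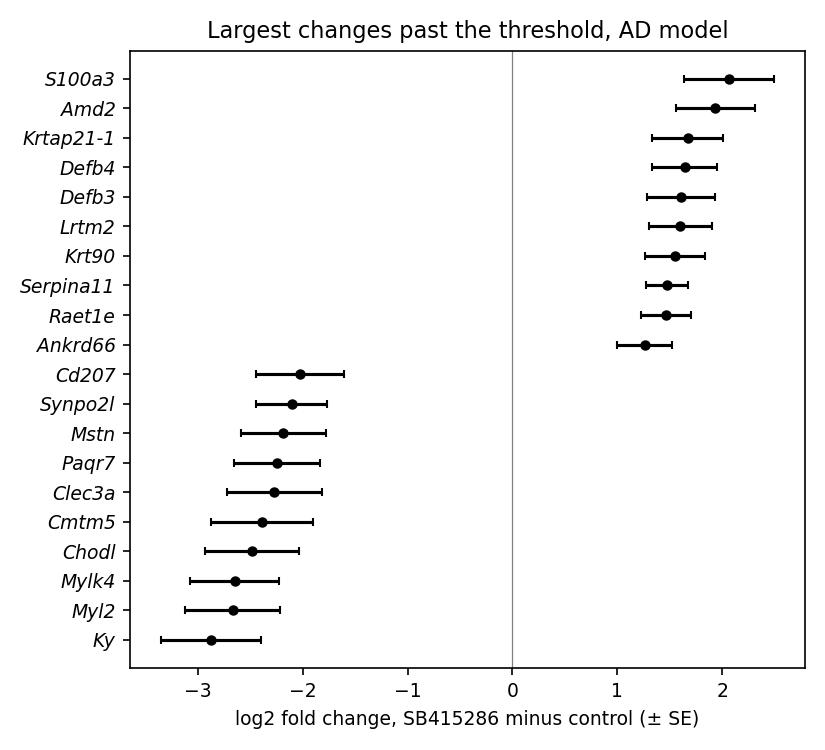
Log2 fold change of SB415286 over control in AD model ears for the 10 largest rises and 10 largest falls among genes past the threshold (points, edgeR estimate; bars, SE; n = 5 per group). Values run from -2.87 for Ky to 2.07 for S100a3.

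Of 33 gene lists tested in the AD model, 19 passed camera, 7 of them shifted up and 12 down. None passed with an estimated correlation (smallest adjusted p = 0.570) or by fry (smallest adjusted p = 0.0741). The Wnt target and feedback list, which beta-catenin activates and which GSK3 restrains, shifted down (median -0.27, camera adjusted p = 0.00472, and adjusted p = 0.570 with an estimated correlation). Of its 22 tested members Lgr6, a receptor of epidermal stem cells, fell by 0.73 ± 0.14 and 21 did not pass, and 6 fell when adjusted over the list alone. The Wnt list score was 4.23 ± 0.034 in controls (SD, n = 5) and 3.96 ± 0.111 with SB415286, lower in 5 of 5 libraries than in every control (exact permutation test, p = 0.00794, the smallest possible, adjusted p = 0.131 over 33 lists). Its call ended without SB415286 library 7 (adjusted p = 0.0517) and without both AD libraries named above (median -0.17, adjusted p = 0.115). The NRF2 antioxidant list shifted up (median 0.25, camera adjusted p = 0.00902, and adjusted p = 0.570 with an estimated correlation). Gsr and Hmox1 rose, 14 of 16 members did not pass, and over the list alone 6 rose and 1 fell. The NRF2 score rose from 6.21 ± 0.122 to 6.50 ± 0.097, above every control in 5 of 5 libraries, and met the same smallest exact p of 0.00794 (adjusted p = 0.131).

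The list of IL-17 and IL-36 axis, antimicrobial and wound keratin genes shifted up (median 0.40, camera adjusted p = 0.0106, and adjusted p = 0.570 with an estimated correlation). Defb4, Defb3, Defb14 and the protease inhibitor Slpi (1.15 ± 0.24) rose, 20 of 24 members did not pass, and 7 rose when adjusted over the list alone. Its call ended without control 6 (adjusted p = 0.121) and without both AD libraries (median 0.18, adjusted p = 0.230). The hair shaft list shifted up (median 1.41, camera adjusted p = 0.0161, and adjusted p = 0.570 with an estimated correlation), although its 1 member past the threshold over all genes, the transcription factor Foxn1, fell by 0.46 ± 0.09. Over this list alone 4 of 12 members rose and Foxn1 fell. Melanocyte genes shifted up (median 0.72, camera adjusted p = 0.000507, and adjusted p = 0.570 with an estimated correlation), with 0 of 8 members past the threshold over all genes and 6 higher when adjusted over the list alone. Mitf, the transcription factor of this lineage, was at 0.57 ± 0.14 and Tyr, which encodes tyrosinase, at 1.15 ± 0.31. Glucocorticoid-induced genes (median 0.58, camera adjusted p = 7.38e-05) and immediate early genes (median 0.30, camera adjusted p = 0.0191) shifted up, each at an adjusted p = 0.570 with an estimated correlation. No member of either passed over all genes, and over the lists alone 0 of 14 and 1 of 18 rose. Angptl4 was at 1.02 ± 0.36, Mt1 at 0.57 ± 0.21, Nr4a3 at 2.48 ± 0.61 and Nr4a1 at 1.27 ± 0.43. Ribosomal protein genes shifted up by a median of 0.24 (76 of 78 positive, 0 past the threshold, camera adjusted p = 6.33e-09, and adjusted p = 0.603 with an estimated correlation).

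Among the lists that shifted down in the AD model, cartilage genes had a median of -1.43 (camera adjusted p = 1.98e-05, and adjusted p = 0.570 with an estimated correlation). Sox9, the transcription factor of chondrocytes, fell by 1.03 ± 0.21, 11 of 12 members did not pass, and 10 fell when adjusted over the list alone. Skeletal muscle genes had a median of -0.99 (camera adjusted p = 7.38e-05, and adjusted p = 0.570 with an estimated correlation), all 17 below 0 and none past the threshold by either adjustment. Pvalb was at -1.87 ± 0.66. The amounts of cartilage and muscle in the samples were not measured, so these 2 shifts cannot be told from less of either tissue. Red blood cell genes (median -1.30, 0 of 5 past the threshold over all genes, 4 lower when adjusted over the list alone) passed camera at an adjusted p = 0.0261, and had an adjusted p = 0.570 with an estimated correlation. T cell markers (median -0.78, all 15 below 0) and interferon-gamma response genes (median -0.62, all 23 below 0) shifted down with 0 members past the threshold by either adjustment. Camera gave an adjusted p = 7.38e-05 and an adjusted p = 1.98e-05, and each list had an adjusted p = 0.570 with an estimated correlation. Cd3g was at -1.29 ± 0.41 and Ciita, the activator of MHC class II genes, at -1.88 ± 0.47. In both lists AD SB415286 library 7 scored above the other injected libraries (T cell 2.81 against 0.51 to 1.22; interferon-gamma 6.73 against 4.15 to 5.01), and control 6 below the other controls (1.54 against 2.06 to 2.97; 5.12 against 5.95 to 6.47). Without library 7 the medians were -1.51 for T cell and -1.38 for interferon-gamma genes. Type 2 inflammation genes shifted down (median -0.46, camera adjusted p = 0.00472, and adjusted p = 0.570 with an estimated correlation), with 0 of 18 members past the threshold over all genes, and 6 lower and 1 higher when adjusted over the list alone. The chemokines Ccl17 and Ccl22 were at -1.92 ± 0.40 (adjusted p = 0.0504) and -1.72 ± 0.40. Without library 7 the type 2 median was -0.82. Dendritic and Langerhans cell markers shifted down (median -0.32, camera adjusted p = 0.0258, and adjusted p = 0.570 with an estimated correlation), with Cd207 lower, 11 of 12 members not past the threshold, and 2 lower when adjusted over the list alone.

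Glycogen genes passed camera at an adjusted p = 0.0440, with a median of -0.17 and an adjusted p = 0.570 with an estimated correlation. Ppp1r3c fell, 13 of 14 members did not pass, and 2 fell when adjusted over the list alone. Cell cycle genes (median -0.33, 21 of 23 below 0), sterol synthesis genes (median -0.18, 16 of 20 below 0) and nuclear respiratory chain genes (median -0.10, 61 of 78 below 0) passed camera at adjusted p = 0.0417, adjusted p = 0.0428 and adjusted p = 0.0261. They had 0 members past the threshold by either adjustment, and with an estimated correlation an adjusted p = 0.798, an adjusted p = 0.718 and an adjusted p = 0.829. The 10 lists that passed in each of the 10 fits without 1 library were NRF2, hair, melanocyte, glucocorticoid, ribosomal, cartilage, muscle, T cell, interferon-gamma and type 2. The other 9 passed in 3 to 9 of these fits. The 14 lists that did not pass had adjusted p of 0.0634 to 0.977. Their medians were -0.68 for fibroblast matrix, -0.37 for sebaceous gland, -0.18 for Schwann cell, -0.15 for type I interferon, -0.02 for barrier, -0.01 for NF-kB, 0.01 for clock, 0.12 for endothelial, 0.22 for itch and 0.38 for neutrophil genes. Mast cell, basophil and eosinophil genes had a median of -0.38. The medians of the anti-inflammatory, macrophage and adipocyte lists (0.03, 0.16 and 0.05) differed in sign from their means (-0.08, -0.04 and -0.21). Car3, of the adipocyte list, fell by 1.62 ± 0.30, and over that list alone 3 members were higher and 2 lower. Lpl was at 1.05 ± 0.24, Pnpla2 at 1.01 ± 0.31 and Fabp4 at 0.85 ± 0.20. Without SB415286 library 7 the NF-kB (median -0.34, adjusted p = 0.00698), type I interferon (-0.47, adjusted p = 0.00419), anti-inflammatory (-0.46, adjusted p = 0.00165) and fibroblast matrix (-0.88, adjusted p = 0.0408) lists passed camera, and the neutrophil median was -0.82. Without control 6 the type I interferon (-0.32, adjusted p = 0.0372), fibroblast matrix (-0.87, adjusted p = 0.0288), sebaceous gland (-0.54, adjusted p = 0.00133) and endothelial (0.22, adjusted p = 0.0142) lists passed. The sebaceous gland and endothelial lists also passed without SB415286 library 4 (adjusted p = 0.0229 and adjusted p = 0.0122), and the Schwann cell list passed without library 4 (-0.21, adjusted p = 0.0453) and without control 1 (-0.25, adjusted p = 0.0159).

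**Figure D2:**
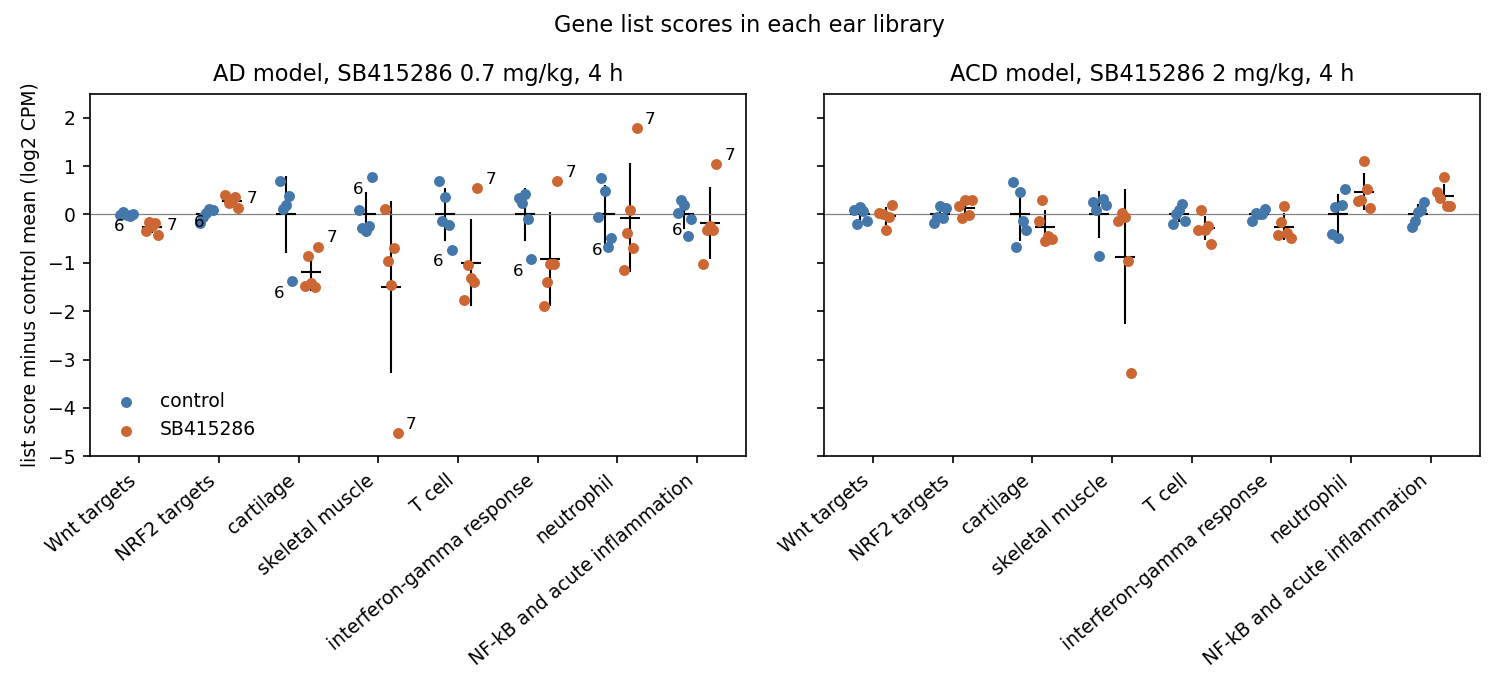
Score of 8 gene lists in each library (points, mean log2 CPM of the list's members minus the control mean of the model; bars, group mean and SD; n = 5 per group) for the AD and the ACD model. In the AD model the Wnt and NRF2 scores of the groups do not overlap, and SB415286 library 7 lies 4.52 below the control mean for skeletal muscle.

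The ACD comparison asked the same of ears from ACD model mice at 2 mg/kg. Transcripts of 3 genes of lung epithelium were higher with SB415286. Sftpc and Sftpb, which encode surfactant proteins, rose by 6.68 ± 0.80 and 3.21 ± 0.25 on the log2 scale (SE, n = 5 per group). Scgb1a1, the secretoglobin of airway club cells, rose by 5.62 ± 0.71. They stayed rare, at 4.79 ± 4.16 CPM (SD, n = 5) for Sftpc, 6.23 ± 1.85 CPM for Sftpb and 8.26 ± 7.29 CPM for Scgb1a1, against 0.0406 ± 0.0228, 0.667 ± 0.183 and 0.159 ± 0.106 CPM in controls. Sectm1a, of the secreted and transmembrane 1 family, fell by 0.61 ± 0.07, from 40.6 ± 2.74 to 26.6 ± 1.57 CPM. In all 4 genes every SB415286 library lay beyond every control.

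These 3 higher and 1 lower gene were all that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment among 15150 tested, at adjusted p = 0.000577 for Sftpb, 0.00680 for Sectm1a, 0.0194 for Sftpc and 0.0258 for Scgb1a1. At an unadjusted p under 0.05 there were 2092 genes, against 758 by chance, and the groups did not overlap for 501 genes (3.31%; chance 0.794%). Summed over 5 libraries, Sftpc had 459 reads with SB415286 and 4 in controls, a ratio of 114 (95% interval 44.1 to 419). Scgb1a1 had 792 and 16 (ratio 49.1, 30.0 to 86.2) and Sftpb had 608 and 66 (ratio 9.13, 7.07 to 12). SB415286 library 5 alone held 222 of the Sftpc and 386 of the Scgb1a1 reads, and without it the changes were 6.00 and 4.93. A list of 20 lung genes was chosen after these values were seen, and 11 of them had enough reads to be tested. For 4, Sftpc, Scgb1a1, Sftpb and Sftpa1, every SB415286 library lay above every control in CPM. For the other lung genes this did not hold. Sftpa1, another surfactant gene, had 53 reads against 2 in total, 26 of them in library 5. Its lowest SB415286 library and its highest control had 2 reads each. The genes with the next smallest p did not pass (adjusted p = 0.0580 each): Smad7, an inhibitor of TGF-beta signalling, at 0.54 ± 0.08, the complement gene C2 at -0.61 ± 0.09, the peptidase gene Erap1 at -0.43 ± 0.07, Lars at -0.45 ± 0.07, the cohesin gene Smc1a at -0.45 ± 0.07 and Vwa5a at -0.39 ± 0.06. Gsk3a was at 0.18 ± 0.05 (adjusted p = 0.181), Gsk3b at 0.07 ± 0.05, Ctnnb1 at -0.09 ± 0.06 and Axin2 at -0.11 ± 0.16. Sftpc lies on chromosome 14 at 70520941 to 70524081 (Entrez Gene 20389), Sftpb on chromosome 6 at 72304610 to 72314373 (20388), Scgb1a1 on chromosome 19 at 9083642 to 9087956 (22287) and Sectm1a on chromosome 11 at 121067395 to 121097153 (209588). With 1 library left out Sftpb and Sectm1a passed in all 10 fits, Sftpc in 5 and Scgb1a1 in 4. The count was 2 without any single control and 7 without SB415286 library 4. It was 18 without library 8 and 13 without libraries 5 and 8, which lay farthest out on the first 2 principal components. It was 394 by DESeq2 (236 higher, 158 lower), which gave no adjusted p for the 3 lung genes. Falls outnumbered rises by limma voom with quality weights (5 higher, 12 lower), under upper quartile scaling (4 and 9) and on FPKM (3 and 9).

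**Figure D3:**
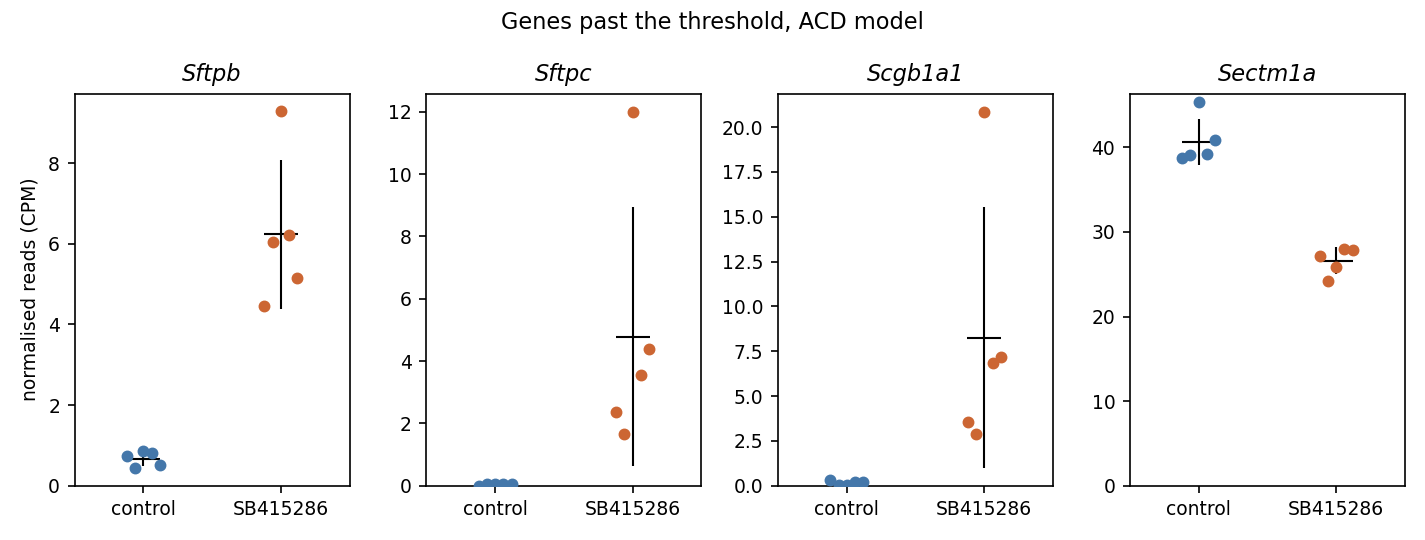
Normalised reads (CPM) of the 4 genes past the threshold in the ACD model, in each control and SB415286 library (points; bars, mean and SD; n = 5 per group). For Sftpc the SB415286 libraries lie between 1.65 and 12 CPM and the controls at or under 0.0533 CPM.

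Of 33 lists in the ACD model 11 passed camera, 5 shifted up and 6 down, and none of their members passed over all genes. With an estimated correlation no list passed (smallest adjusted p = 0.877), nor by fry (smallest adjusted p = 0.506). NF-kB targets and acute inflammatory genes shifted up (median 0.33, camera adjusted p = 2.08e-06, and adjusted p = 0.877 with an estimated correlation), with 24 of 27 members above 0 and 8 higher when adjusted over the list alone. Ptgs2, which encodes cyclooxygenase 2, was at 0.76 ± 0.17 and the neutrophil chemokine Cxcl3 at 0.97 ± 0.24. Immediate early genes shifted up (median 0.30, camera adjusted p = 2.08e-06, and adjusted p = 0.877 with an estimated correlation), with 16 of 18 members above 0 and 6 higher when adjusted over the list alone. Ier3 was at 0.71 ± 0.14. Neutrophil markers (median 0.48, camera adjusted p = 0.000123) and clock genes (median 0.13, camera adjusted p = 0.00612) shifted up, each at an adjusted p = 0.877 with an estimated correlation. Over the lists alone 0 of 16 and 1 of 14 members rose. Clec4d was at 0.72 ± 0.23 and Nr1d1, a clock repressor, at 0.75 ± 0.13. Ribosomal protein genes shifted up by a median of 0.05 (camera adjusted p = 0.000986, and adjusted p = 0.882 with an estimated correlation), with 56 of 79 members above 0.

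Interferon-gamma response genes shifted down in the ACD model (median -0.22, camera adjusted p = 0.000283, and adjusted p = 0.877 with an estimated correlation), with 23 of 26 members below 0 and 1 lower when adjusted over the list alone, the MHC class II gene H2-Aa at -0.62 ± 0.14. T cell markers (median -0.26, 14 of 15 below 0, camera adjusted p = 0.000318), macrophage and monocyte markers (median -0.25, 15 of 16 below 0, camera adjusted p = 0.00116) and cell cycle genes (median -0.10, 22 of 23 below 0, camera adjusted p = 0.000924) shifted down. Each had an adjusted p = 0.877 with an estimated correlation, and 0, 2 and 1 of their members were lower when adjusted over the list alone. Lck was at -0.45 ± 0.14, Adgre1, which encodes the macrophage marker F4/80, at -0.79 ± 0.19 and Top2a at -0.49 ± 0.10. Barrier genes (median -0.20, 29 of 31 below 0, camera adjusted p = 0.00163) and skeletal muscle genes (median -0.49, all 17 below 0, camera adjusted p = 0.000924) shifted down with 0 members past the threshold over the list alone, each at an adjusted p = 0.882 with an estimated correlation. For muscle, ACD SB415286 library 8 scored 1.90, against 4.20 to 5.20 in the other injected libraries. The amount of muscle in the samples was not measured here either. Without library 8 the muscle, clock and ribosomal lists no longer passed (adjusted p = 0.121, adjusted p = 0.0967 and adjusted p = 0.295), and without library 5 the barrier list did not (adjusted p = 0.218).

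The 22 lists that did not pass in the ACD model had adjusted p of 0.0867 to 0.879. Their medians were -0.34 for cartilage, -0.22 for hair, -0.20 for sebaceous gland, -0.17 for melanocyte, -0.12 for adipocyte, -0.11 for endothelial, and -0.09 for dendritic cell genes. They were -0.08 for Schwann cell, -0.07 for fibroblast matrix and -0.06 for mast cell, basophil and eosinophil genes. They were -0.02 for sterol synthesis, 0.02 for glucocorticoid-induced, 0.05 for type 2 inflammation, 0.05 for anti-inflammatory, 0.12 for NRF2 and 0.16 for IL-17 axis genes. For the Wnt (-0.02), type I interferon (0.01), itch (-0.05), glycogen (0.03), red blood cell (-0.09) and respiratory chain (0.01) lists the median differed in sign from the mean or the test.

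The next comparison asked whether the effect of SB415286 differed between the models, whose doses also differed. The lung genes differed most: the effect in the ACD model exceeded that in the AD model by 7.23 ± 1.2 for Sftpc, by 6.70 ± 1.00 for Scgb1a1 (-1.06 in AD, 5.62 in ACD) and by 3.20 ± 0.41 for Sftpb (0.02 and 3.21; n = 5 per group). Sox9, the chondrocyte factor, was at -1.03 in AD and 0.25 in ACD, a difference of 1.29 ± 0.23. In ACD it was the 1 member of the cartilage list above 0, with 12 below (list median -0.345). Its rise there therefore does not stand for cartilage genes. The proteoglycan gene Gpc1 was at -0.67 in AD and 0.18 in ACD, a difference of 0.85 ± 0.13. Effects were lower in ACD for the dynein chain gene Dynlt1c (0.77 in AD, -0.06 in ACD, difference -0.82 ± 0.14), the lipid transfer gene Osbpl9 (0.59 and 0.03, -0.56 ± 0.10) and 4931406C07Rik (0.89 and -0.26, -1.14 ± 0.20), the last chosen after its values were seen.

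These 5 higher and 3 lower differences were all that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15700 genes, with adjusted p of 0.00439 for Sftpb to 0.0495 for Sox9. At an unadjusted p under 0.05 there were 1975 genes, against 785 by chance. Gsk3a (0.22 ± 0.09), Gsk3b (-0.07 ± 0.15), Ctnnb1 (-0.16 ± 0.10) and Axin2 (0.31 ± 0.28) did not pass. Gpc1 lies on chromosome 1 at 92831645 to 92860211 (Entrez Gene 14733), Sox9 on chromosome 11 at 112782210 to 112787757 (20682), Osbpl9 on chromosome 4 at 109061145 to 109202272 (100273) and Dynlt1c, which has near copies, on chromosome 17 at 6601779 to 6607891 (100040563). Without AD SB415286 library 7 and AD control 6 the count was 2117, and all 8 genes remained among them. It was 312 without the former and 234 without the latter. Both lay toward the other group, so these higher counts and the kept genes are no added support. The count was 19 without AD SB415286 library 2 and 5 without ACD SB415286 library 8. It was 4 without AD SB415286 library 4 or 6, ACD SB415286 library 7 or ACD control 1. It was 3 without AD SB415286 library 3, AD control 5 or ACD control 4, 5 or 6, and 1 without ACD control 3. In these 20 fits Sftpb passed in 20, Scgb1a1 and Gpc1 in 19, Dynlt1c in 11, Sftpc in 10, Osbpl9 in 5 and Sox9 in 2. By DESeq2 163 genes passed, by limma voom with quality weights 1187, without the filter 5 and under upper quartile scaling 14.

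Of 34 lists tested for the difference 12 passed camera, 7 with a higher effect in the ACD model and 5 with a lower one, and none passed with an estimated correlation (smallest adjusted p = 0.706) or by fry (smallest adjusted p = 0.327). Cartilage genes (median 1.2, camera adjusted p = 0.000536), type 2 inflammation genes (median 0.48, camera adjusted p = 0.000881) and Wnt targets (median 0.32, camera adjusted p = 0.0127) were relatively higher in ACD, each at an adjusted p = 0.706 with an estimated correlation. Sox9 passed over all genes and 1 of 13 cartilage genes, 4 of 19 type 2 genes and 1 of 23 Wnt genes were higher when adjusted over the list alone. Red blood cell (median 1.28), T cell (0.45), interferon-gamma (0.44) and NF-kB genes (0.32) were relatively higher too, at camera adjusted p = 0.0345, adjusted p = 0.00175, adjusted p = 0.000536 and adjusted p = 0.00175. Each of these 4 lists had an adjusted p = 0.775 with an estimated correlation and 0 members past the threshold by either adjustment. Hair genes (median -1.81, camera adjusted p = 0.00115), melanocyte genes (-0.98, camera adjusted p = 0.000536), glucocorticoid-induced genes (-0.59, camera adjusted p = 0.000536) and endothelial genes (-0.25, camera adjusted p = 0.0125) were relatively lower in ACD, each at an adjusted p = 0.706 with an estimated correlation. Over the lists alone 1 hair gene was higher and 2 lower, 2 melanocyte genes were lower, and 0 glucocorticoid-induced or endothelial genes passed. Ribosomal protein genes (-0.18, camera adjusted p = 7.49e-05) were relatively lower as well, at an adjusted p = 0.775 with an estimated correlation. B cell markers, tested in this comparison only, did not pass (median -1.03, adjusted p = 0.110). The medians of the adipocyte and immediate early lists (-0.21 and 0.02), which did not pass, differed in sign from their means (0.10 and -0.17). Without AD SB415286 library 7 the medians were 0.86 for type 2, 1.17 for T cell, 1.16 for interferon-gamma and 0.95 for NF-kB genes. The neutrophil list then passed camera (1.23, adjusted p = 0.000584), as it did without AD control 5 (0.24, adjusted p = 0.0463). Without library 7 the type I interferon (0.53), anti-inflammatory (0.54), barrier (-0.28), dendritic cell (0.40) and fibroblast matrix (0.85) lists passed too. The macrophage, respiratory chain and dendritic cell lists passed in 9, 7 and 6 of the 20 fits without 1 library. The endothelial list no longer passed without AD SB415286 library 7 (adjusted p = 0.0667) or ACD SB415286 library 8 (adjusted p = 0.0518). The Wnt list no longer passed without AD SB415286 library 7 (adjusted p = 0.103), without ACD SB415286 library 8 (adjusted p = 0.0583) or without both AD libraries (median 0.23, adjusted p = 0.175), and the red blood cell list passed in only 4 of 20 fits without 1 library.

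The last comparison asked whether the models responded alike. Of the genes called in the AD model, 70 of 87 rises measured in both (80.5%) were above 0 in ACD, where 48.1% of all genes were, and 72 of 92 falls (78.3%) were below 0, where 51.9% of all genes were. Across 14687 genes tested in both, the log2 fold changes correlated at a Pearson r of 0.293 and a Spearman rho of 0.300, and 60.2% had the same sign. Genes are not independent replicates. Of 100 pairs of splits of the libraries, the real pair among them, 6 gave a correlation of at least this size in either sign. Each pair mixed injected and control libraries in the same way in both models, so a shared effect would also enter these correlations. The comparison therefore cannot decide about chance, which is not excluded. The chance values below assume independent genes. No gene passed in both models, against 0.0119 by chance for rises and 0.00626 for falls. At an unadjusted p under 0.05, 269 genes were higher in both, against 108 by chance, and 151 were lower in both, against 96.8 by chance. Nr4a3, of the immediate early list, was at 2.48 ± 0.61 in AD and 0.52 ± 0.10 in ACD, and Gsr, of the NRF2 list, at 0.96 ± 0.15 and 0.40 ± 0.13.

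**Figure D4:**
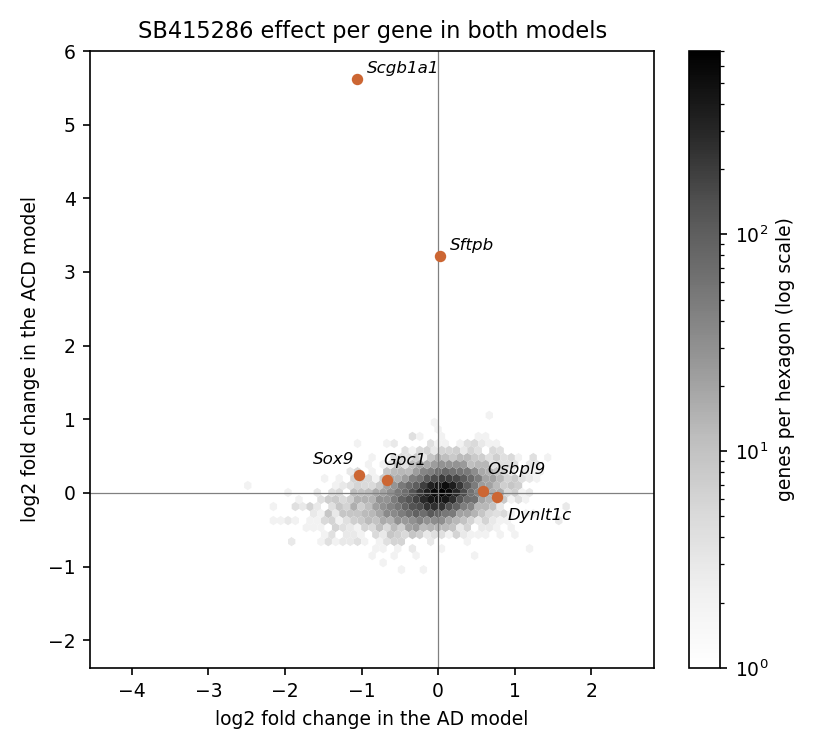
Log2 fold change of SB415286 over control in the AD model (horizontal) and the ACD model (vertical) for 14687 genes (grey hexagons, genes per hexagon on a log scale), with genes whose effects differ between the models in orange. Pearson r is 0.293; Sftpc had no AD fit of its own and is not drawn.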

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

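The tests of the AD library pair, of the lung genes and of the Wnt list, and the comparison of the AD and ACD gene counts with other splits, all 126 among them, were chosen after the results were seen.

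Each list score and each named gene was checked in each group for a library far from the other 4. Such a library was found in 8 of 132 checks of list scores, 5 of 76 checks of named genes and 1 of 4 of library totals. Chance marks about 1 in 20 of such checks. AD control 6 was apart for cartilage genes (3.38 mean log2 CPM, others 4.87 to 5.45), clock genes (5.40, others 4.75 to 4.93), IL-17 axis genes (6.64, others 7.11 to 7.29), Cmtm5 (-0.66 log2 CPM, others 1.26 to 1.78) and Clec3a (2.62, others 4.62 to 5.38). AD SB415286 library 7 was apart for clock genes (4.57, others 5.00 to 5.15) and for Axin2 (4.11, others 4.82 to 5.04). ACD control 4 was apart for ribosomal protein genes (9.42, others 9.20 to 9.24) and skeletal muscle genes (4.30, others 5.26 to 5.47). AD control 5 was apart for itch genes (3.53, others 3.77 to 3.85), AD SB415286 library 6 for sterol synthesis genes (6.60, others 6.21 to 6.28) and AD SB415286 library 4 for Krtap21-1 (2.34, others 1.06 to 1.31). AD SB415286 library 2 had the lowest total, 18.2 M counts (M, mega; others 20.4 to 20.9 M), and ACD control 1 the lowest Sftpc level (-3.30, others -2.73 to -2.69), at 0 reads against 1 in each of the others.

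A tested difference between the models in the effect of SB415286 was found for Sftpc (7.23), Scgb1a1 (6.70), Sftpb (3.20), Sox9 (1.29), Gpc1 (0.85), Osbpl9 (-0.56), Dynlt1c (-0.82) and 4931406C07Rik (-1.14). By camera the lists that differed, none of them with an estimated correlation (smallest adjusted p = 0.706), were red blood cell (1.28), cartilage (1.2), type 2 inflammation (0.48), T cell (0.45), interferon-gamma (0.44), Wnt (0.32), NF-kB (0.32), ribosomal protein (-0.18), endothelial (-0.25), glucocorticoid-induced (-0.59), melanocyte (-0.98) and hair genes (-1.81).

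The first pattern is that AD SB415286 library 7 and AD control 6 lay on the side of the other group. On an axis from the control mean (0) to the SB415286 mean (1), set by the other libraries over 500 genes, library 7 was at 0.234 and control 6 at 0.789, with the other 8 libraries on their own side of 0.5. A fault of depth is argued against by their totals of 20.4 and 20.5 M, within the range of the other 8. An exchange of these 2 labels stays open, as does a difference between these animals: with the labels exchanged 8 lists parted the groups completely, against 2 (Wnt and NRF2, neither among the 8) as deposited, but the pair was chosen for its position, so this count restates it. No label was changed, and no biological explanation was tested.

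The second pattern is the rise of 4 lung genes in the ACD SB415286 libraries. The other genes of the list of 20 did not part the groups in this way. Only 11 of the 20 had enough reads to be tested, and 6 averaged at least 5 CPM in controls. A small amount of lung RNA might not show in such genes, so they do not argue against it. Reads or RNA of lung in these libraries would keep the genes at 1 ratio across libraries, and Sftpc, Scgb1a1 and Sftpa1 did so within counting error (exact test by simulation, p = 0.821). For Sftpb, reads above the control level were 0.721 to 3.27 times those of Sftpc, more than counting error (exact test by simulation, p = 1e-05, the smallest possible with this simulation), but that test leaves out the spread between animals, so it excludes nothing. Lung material and an effect of SB415286 on these genes in the ear both stay open for all 4 genes.

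The third pattern is the lower Wnt list in the AD SB415286 libraries, where GSK3 inhibition was given. Less cartilage in the samples would need the Wnt score to follow the cartilage score with a slope of 0.227, and within groups the slope was -0.027 (-0.083 to 0.004 with 1 library left out). Less skeletal muscle would need a slope of 0.179, and within groups it was 0.034 (-0.046 to 0.06). In the groups as deposited, neither slope reached the needed one with any 1 library left out. These ranges are not intervals of error, and an exchange of labels in the pair above would change the groups. The slopes therefore cannot decide whether either tissue is the whole cause. With these slopes the Wnt difference of -0.27 was -0.30 after adjustment for cartilage and -0.22 after adjustment for muscle. Less cartilage, less muscle, an effect of SB415286 and a change of labels in the pair above all stay open.

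Among 100 splits drawn, the real split gave the most genes in the AD model (187, highest other 3) and in the ACD model (4, highest other 1). The AD draw lacked the split that exchanges the pair, and over all 126 splits this one gave 3813 genes, so that 2 of 126 (1.59%) reached the real count. The pair was chosen for its position, so a high count on its exchange restates that position and does not support an exchange of labels. Few splits reached the real count, but this comparison was chosen after the count was seen, so chance is not excluded by it. A split with several times the real count points to structure of the samples. In the ACD model the real split gave the most of all 126, so that 1 of 126 (0.794%) reached the real count. This comparison was chosen after the count was seen. Of the 4 genes 3 are lung genes that may share 1 source. The count therefore does not stand for 4 separate changes, and it cannot tell lung material from an effect of SB415286. For the difference between the models 3 of 100 splits reached the real count of 8. These 100 were drawn from many more, so the share is imprecise and chance is not excluded by it. The highest other split gave 1539 genes, several times the real count, which points to structure of the samples. That split placed AD control 6 with the other 4 AD SB415286 libraries and library 7 with the controls, and mixed the ACD groups. For lists chance cannot be excluded: 19 of 100 splits reached the real count of 19 lists in AD (highest other 23), 66 reached 11 in ACD (highest other 21) and 65 reached 12 for the difference (highest other 23). Nor can it be excluded for the correlation of 0.293 between the models, a size reached by 6 of 100 splits (highest other 0.357). These splits mixed injected and control libraries in the same way in both models. A shared effect would also enter their correlations, so they cannot decide about chance. Over all 126 splits of the AD libraries the genes without overlap numbered 704 for the real split and 2427 for the split that exchanges the pair, the highest, and 3 splits reached 704. In the ACD model the real split had the most, 501.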

How the results depend on the processing

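The fits that left out 2 libraries together, kept the authors' subset or rescaled the lists were chosen after the results were seen. The AD pair, SB415286 library 7 and control 6, was left out for lying toward the other group. Higher counts and kept calls without it are therefore no added support. Counts of changed genes depended on the setting, and except where fewer libraries or other genes were tested the cause was not tested. In the AD model the 187 genes were 1235 by DESeq2, 3588 by limma voom with quality weights, 48 without a filter, 1461 in 1 fit of all libraries, 3894 without SB415286 library 7 and control 6, and 0 to 1423 with 1 library left out. In the ACD model the 4 genes were 394 by DESeq2, 17 by limma voom, 13 under upper quartile scaling, 12 on FPKM with either offset, 2 in the libraries behind the authors' means (none of the 4 among them), 13 without SB415286 libraries 5 and 8, and 2 to 18 with 1 library left out. The 8 genes of the difference were 163 by DESeq2, 1187 by limma voom, 14 under upper quartile scaling, 5 without a filter, 2117 without the AD pair, and 1 to 312 with 1 library left out. DESeq2 gave no adjusted p for 12 of the named ACD genes, Sftpb, Sftpc and Scgb1a1 among them. With the title number as a replicate block 0 genes passed in AD (2255 at an unadjusted p under 0.05), 1 in ACD and 1 for the difference. Only numbers 2, 4 and 6 in AD and 3, 4 and 5 in ACD occurred in both groups. The block fit thus rested on these libraries alone, so its lost calls partly reflect fewer libraries. Shared numbers correlated at -0.20 to 0.25 and 1 of 6 matched its own number best, so the numbers did not pair the libraries. The 19 AD, 11 ACD and 12 difference lists were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry. With 1 library left out they were 14 to 21, 10 to 15 and 12 to 18, and the difference lists were 20 without the AD pair. Medians of passing lists that moved by over 1.5 times with 1 library left out ran, in AD, from -0.82 to -0.34 for type 2, -1.51 to -0.54 for T cell, -1.38 to -0.45 for interferon-gamma, 0.19 to 0.50 for IL-17 axis, 0.12 to 0.37 for immediate early, 0.46 to 0.91 for glucocorticoid-induced, -0.50 to -0.16 for cell cycle, -0.28 to -0.12 for glycogen, -0.26 to -0.08 for sterol synthesis and -0.17 to -0.01 for respiratory chain genes. In ACD they ran from -0.37 to -0.15 for interferon-gamma, -0.30 to -0.08 for barrier, -0.12 to -0.06 for cell cycle, 0.08 to 0.23 for clock, 0.24 to 0.60 for neutrophil, -0.72 to -0.21 for muscle and 0.02 to 0.09 for ribosomal protein genes. For the difference they ran from 0.28 to 0.86 for type 2, 0.25 to 1.17 for T cell, 0.24 to 1.16 for interferon-gamma, 0.22 to 0.95 for NF-kB, 0.81 to 1.93 for red blood cell and -0.25 to -0.09 for ribosomal protein genes. Lists not past the threshold gained a call in 12 of 140 AD, 19 of 220 ACD and 44 of 440 difference fits. The AD barrier list, not past the threshold as reported (median -0.02), reversed to 0.32 without the pair (adjusted p = 0.0236). Upper quartile scaling ended the calls of the AD cell cycle (adjusted p = 0.0675) and glycogen (adjusted p = 0.0558) lists. The correlation of 0.293 between the models was 0.222 to 0.353 with 1 library left out and 0.229 without the AD pair. Of 28 named AD genes past the threshold, all 28 kept their call under DESeq2, limma voom and without the pair, 22 under upper quartile scaling, 17 of 21 on FPKM, 8 without a filter and 0 with the block. With 1 library left out, 57 of their 280 calls were kept and 223 lost. The 4 ACD genes kept 29 of 40 calls and lost 11, and the block kept 1 of the 4. The 7 difference genes named beforehand kept 86 of 140 and lost 54, and the block kept 0 of the 7. In simulated data at this depth 77% (AD), 82% (ACD) and 64% (difference) of genes changed by 1 on the log2 scale were found. Those genes were simulated independently of each other and without libraries out of place, so the real rates may differ.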

Other observations

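The lists and values in this part were chosen after the results were seen. Control scores of the 2 models are given side by side here. In mean log2 CPM (SD, n = 5 per group) they were 5.51 ± 0.431 in ACD and 3.47 ± 0.611 in AD for neutrophil markers, 6.71 ± 0.206 and 4.52 ± 0.297 for NF-kB targets and acute inflammatory genes, and 3.62 ± 0.166 and 2.27 ± 0.552 for T cell markers. Barrier genes stood at 7.00 ± 0.212 in ACD controls and 8.91 ± 0.368 in AD controls, and Schwann cell genes at 3.79 ± 0.285 and 5.14 ± 0.167. The tables were made separately for each model, and these levels, which rest on 11 AD and 16 ACD members for neutrophils, were not tested against each other.

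Liver genes were high in 1 AD control. Alb, which encodes albumin, was at 930 CPM in control 4, against 20.2 to 59.0 CPM in the other controls and 0.0553 to 143 CPM in the SB415286 libraries. Apoa1, an apolipoprotein gene, was at 91.6 CPM against 2.81 to 8.35 CPM in the other controls, and Ttr, which encodes transthyretin, at 75.1 CPM against 0.969 to 3.54 CPM. Control 4 had the highest value of the 10 AD libraries for 19 of 20 liver genes.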
